A study of Mus musculus with 34 samples.

How the data were processed

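RNA was measured in dissociated lumbar dorsal root ganglion cells of mice 8 to 12 weeks old, enriched for neurons on a 20% Percoll gradient, 3 days after a sciatic nerve crush, per the labels. Libraries were made from total RNA with a stranded kit and sequenced in pairs, per the labels' protocols. The deposited table holds raw counts per gene for 48795 Ensembl genes in 34 libraries. Reads were split with bcl2fastq 2.20, aligned with STAR to GRCm38 and counted with HTSeq, per the submitters' processing notes. The versions of STAR and HTSeq, the annotation release and the strand setting are not given in the sources used here, so counts of genes that overlap on opposite strands, and of near-identical copies such as the ribosomal protein, tubulin and Serpina3 genes, are uncertain. Because the counts are of total RNA, they hold unspliced and ribosomal spacer reads. Only whole-gene counts were used, so the deleted exon of Atf3 was not measured. Symbols were matched for 48349 gene IDs; the 446 unmatched IDs hold 0.043% of the counts. Gene coordinates come from the GENCODE annotation of GRCm38. Rows with no gene ID numbered 0, as did columns of no sample.

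The series title concerns B2-SINE transcription. These elements were not analysed here, and the planned test of them was not run.

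Groups were formed from the labels, by genotype and side, with the animal number as the replicate. The controls are mice with any mix of Cre and floxed alleles that leaves ATF3 intact. Sex labels were compared with sex-linked genes, and 0 libraries went against their label. No libraries were identical, and the closest pair within a group differed by 8.61 times the sampling noise (chi-square per degree of freedom), so all were kept.

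Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, and the robust quasi-likelihood F-test in 1 model of the 4 groups with sex as a covariate over all 34 libraries. This left 19565 genes, which hold 99.97% of the counts. Adjusted p is by Benjamini-Hochberg, with a threshold of 0.05, and the SE of a log2 fold change is its size over the square root of F. The comparisons were injured against naive in each genotype, cKO against wt on each side, and the difference of the injury effects. Both sides of an animal are paired by the animal itself. The deviations of its libraries from the group means had a median correlation of 0.558 over 17 pairs (lowest 0.047, highest 0.8; over 0.1 in 16), and 10 injured and 12 naive libraries correlated best with their own partner. The fit with the mouse as a block was an alternative for the injury effects and their difference.

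The response size was the slope, across signature genes, of a mouse's log2 injured to naive ratio (CPM with a prior count of 2) on the mean ratio of the signature mice. Signature genes passed limma 3.58.1 on the paired differences of the wt mice with a mean log2 ratio of at least 1 in size; each wt mouse was left out of its own signature, and a cKO slope is the mean over the 9 signatures that leave out 1 wt mouse. Slopes were compared by a two-sided exact permutation test.

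Before the data were examined, 26 gene lists were fixed: regeneration-associated genes, nociceptor identity, mechanoreceptor and proprioceptor identity, voltage-gated potassium channels, neuropeptides, cholesterol synthesis, integrated stress response, AP-1 family, neuronal injury and death, ribosomal proteins, RNA polymerase III, interferon response, tubulins and neurofilaments, immediate early genes, pan-neuronal genes, and markers of satellite glia, Schwann cells, macrophages, neutrophils, T and B cells, endothelial cells, fibroblasts, pericytes, red blood cells, skeletal muscle and proliferating cells. They were tested with camera (preset correlation 0.01, and estimated), with Benjamini-Hochberg adjustment over the lists of a comparison; fry was run for direction and is not printed. The same holds for the rule for named genes: per comparison the 6 largest changes of each sign that passed, reached 5 CPM in the higher group, had no predicted-gene name and, for the injury effects, had the same sign in every mouse; Atf3; and list members, up to 4 per list by p, or any with its value. Some genes that this rule takes are not reported here. Tests, groups and the alternatives not named as added were fixed at the same time.

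Depth was 35732193 to 77632944 counts per library, and intervals on levels come from the spread between mice. A group total of 3 counts or fewer was taken as the floor, where no fold is printed. The share of counts in 3 ribosomal RNA spacer genes ran from 5.02% to 20.03% and split the mice into 6 with up to 10.27% and 11 with at least 13.67%. Both libraries of a mouse fell on the same side. The low set held 3 cKO and 3 wt mice and the high set 5 cKO and 6 wt mice. The only females of the low set were cKO-152 and wt-175, and the only males of the high set cKO-194 and wt-195. The ribosomal sets thus overlap with sex, and fits by set and by sex are not separate checks. The mitochondrial share was 0.94% to 1.56% in the low and 0.34% to 0.85% in the high set. The labels name no batch; the split was used as one, and fits within each set and with the set as a covariate were added after seeing the data.

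The alternatives were median-ratio size factors, no filter, DESeq2 1.42.0, the mouse as a block, no sex covariate, only the libraries compared, females only, males only, and each mouse left out in turn; added after seeing the data were the ribosomal sets and the omission of mice cKO-131 and wt-150. The test was checked on simulated counts in which 200 genes changed by known folds. Of 1.5-fold changes 86.6% were recovered for injury in wt, 79.1% for injury in cKO, 80.6% and 83.6% for genotype on the injured and naive sides and 53.7% for the difference of injury effects; of 2-fold changes 95.5%, 94%, 89.6%, 92.5% and 92.5%. These draws were independent between libraries. A simulated response ratio of 0.4 came back as 0.368 and a ratio of 1 as 1.01. In a further simulation, cKO libraries were drawn 10 times with the observed wt means, so that the injury effect was the same in both genotypes. The chance deviations of the wt libraries enter these draws, so they do not show what sharing the wt libraries gives.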

Results

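RNA was counted in neurons enriched from lumbar dorsal root ganglia, which hold the cell bodies of sensory neurons, 3 days after a sciatic nerve crush. Each of 17 mice gave 1 library from the crushed side and 1 from the other side, called naive. In 9 control mice (ATF3-wt) the gene for ATF3, a transcription factor that sensory neurons switch on after axon injury, was intact. In 8 mice (ATF3-cKO) both copies of Atf3 carried a floxed exon, which Cre recombinase driven from the sensory neuron gene Avil deletes. The groups were 9 wt naive, 9 wt injured, 8 cKO naive and 8 cKO injured libraries. Library totals ran from 35732193 to 77632944 counts, with medians of 54645966, 61165248, 56797758 and 54913553 in the same order, and 19565 genes were tested. Levels are CPM (library-scaled counts), as mean ± SD over the mice of a group. Mice are named by genotype and the animal number of the labels, as in cKO-131.

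Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039 in GRCm38) was counted at 125 ± 30.8 CPM in naive wt, 364 ± 145 CPM in injured wt, 119 ± 25.6 CPM in naive cKO and 264 ± 59.6 CPM in injured cKO libraries. It rose with injury in 9 of 9 wt mice, with a log2 fold change of 1.56 (SE 0.19, adjusted p = 1.87e-07) in edgeR's quasi-likelihood test, and in 8 of 8 cKO mice, with 1.16 (SE 0.20, adjusted p = 0.000283). Between genotypes on the injured side the log2 fold change was -0.46 (SE 0.19, adjusted p = 0.135), which did not pass. The count covers the whole gene and the deletion removes exon 3 alone, so it does not check the deletion. Avil, whose locus drives Cre, lay between 432.5 and 555.5 CPM in 20 of the 22 libraries labelled Cre-positive and between 792.5 and 1036 CPM in 10 of the 12 labelled Cre-negative. The exceptions were both libraries of mouse cKO-131, an ATF3-cKO mouse, at 83.4 and 88.8 CPM, and both of mouse wt-150, labelled Cre-negative, at 499.2 and 516.9 CPM. All 6 control females were labelled Cre-negative and all 3 control males Cre-positive, so sex and Cre cannot be separated among the controls.

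**Figure D1:**
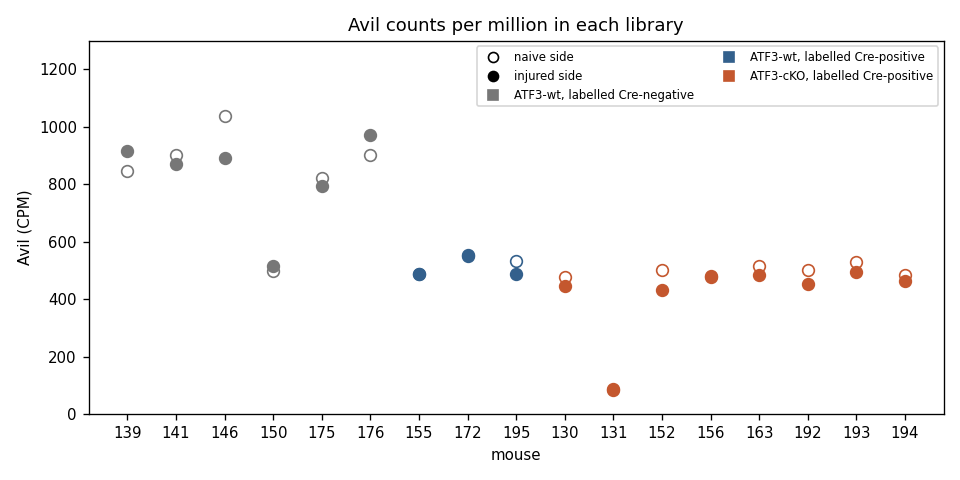
Avil level of each library, in CPM, by mouse, with the naive and the injured side as separate points. Mouse wt-150 lies at 499.2 and 516.9 CPM among the Cre-positive mice, and mouse cKO-131 lies below all others at 83.4 and 88.8 CPM.

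The injured and naive sides of ATF3-wt were compared to find which genes respond to axon injury when ATF3 is intact. Sprr1a, a small proline-rich protein of regrowing axons (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), rose from 0.163 ± 0.105 to 198 ± 140.6 CPM, a log2 fold change of 10.17 (SE 0.49, adjusted p = 1.98e-16). The neuropeptide gene Npy rose from 0.258 ± 0.442 to 52.8 ± 33.8 CPM and the serotonin transporter gene Slc6a4 from 0.149 ± 0.0530 to 20.8 ± 15.0 CPM, with log2 fold changes of 7.66 and 7.11. These genes rose in 9 of 9 mice, and Lipn, Fgf3 and the cholecystokinin receptor gene Cckbr, at 8.95, 7.96 and 6.80 on the log2 scale, completed the 6 largest named rises. Lipn had 8 counts over the 9 naive libraries, so its fold is imprecise. The largest named falls were smaller. Cyp26b1, which degrades retinoic acid, fell by 1.29 on the log2 scale, the matrix protein gene Comp fell by 1.23, and Rem2, Sema5b, Chrnb3 and Glb1l2 had log2 fold changes between -1.07 and -1.02.

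Of the regeneration-associated genes 29 of 32 measured members rose and none fell (29 adjusted over the list alone; camera adjusted p = 3.2e-44, and adjusted p = 0.00701 with an estimated correlation). The neuropeptide gene Gal rose from 23.2 ± 9.51 to 213 ± 162.5 CPM, the growth cone gene Gap43 from 157 ± 25.9 to 387 ± 165 CPM, the transcription factor gene Sox11 from 29.0 ± 5.54 to 187 ± 107 CPM, and Csf1, a growth factor of macrophages, from 26.3 ± 3.82 to 144 ± 83.6 CPM, each in 9 of 9 mice. Of the voltage-gated potassium channel genes 25 of 30 fell and 2 rose (27 and 2 adjusted over the list alone; camera adjusted p = 3.3e-12, and adjusted p = 0.076 with an estimated correlation). Kcna2 fell from 550 ± 67.3 to 307 ± 73.5 CPM, and Kcns1 fell by 0.75 on the log2 scale. Of the nociceptor genes 14 of 31 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.001, and adjusted p = 0.532 with an estimated correlation). The sodium channel gene Scn10a fell by 0.48 and the cold receptor gene Trpm8 by 0.61 on the log2 scale, while Gfra1, a receptor for glial cell line-derived neurotrophic factor, rose by 1.77. Of the mechanoreceptor and proprioceptor genes 12 of 20 fell and 1, the osteopontin gene Spp1, rose (12 and 1 adjusted over the list alone; camera adjusted p = 4.89e-06, and adjusted p = 0.252 with an estimated correlation). With 1 mouse left out in turn, the count of potassium channel genes that rose stayed at 2 without cKO-131, cKO-163 or cKO-194. It was 0 without cKO-130, wt-172, wt-175 or wt-176 and 1 without wt-139, wt-141, wt-146, wt-150, cKO-152, wt-155, cKO-156, cKO-192, cKO-193 or wt-195. The nociceptor genes that rose numbered 2 without wt-150, and those that fell 9 without wt-172.

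Of the ATF4 targets of the integrated stress response 14 of 27 rose and 3 fell (19 and 3 adjusted over the list alone; camera adjusted p = 0.000134, and adjusted p = 0.252 with an estimated correlation), with Chac1 at 1.34 and the asparagine synthetase gene Asns at 0.35 on the log2 scale. Of the tubulin and neurofilament genes 9 of 21 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000431, and adjusted p = 0.532 with an estimated correlation). Tubb6 rose from 6.32 ± 0.492 to 84.5 ± 46.8 CPM. Of the cholesterol synthesis genes 8 of 25 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.524 with an estimated correlation). Those that fell numbered 2 without cKO-130 or cKO-152, and in males the list did not pass (adjusted p = 0.051). Hsd17b7, an enzyme of that pathway, rose from 52.5 ± 9.17 to 181 ± 72.4 CPM. Of the neuropeptide genes 7 of 17 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.000858, and adjusted p = 0.132 with an estimated correlation). Of the neuronal injury and death genes 9 of 19 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.000488, and adjusted p = 0.202 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a rose by 2.14 on the log2 scale. Of the ribosomal protein genes 24 of 76 rose (29 adjusted over the list alone; camera adjusted p = 0.000125, and adjusted p = 0.532 with an estimated correlation).

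Lists that did not pass in wt were the AP-1 family, with 4 of 13 higher and 1 lower (4 and 1 adjusted over the list alone), and the RNA polymerase III genes, with 6 of 29 higher and 2 lower (6 and 3 adjusted over the list alone). The AP-1 median was -0.09 and its mean 0.33 on the log2 scale, and camera leaned to a rise. The immediate early genes, with 2 of 19 higher and 2 lower, and the pan-neuronal genes, with 6 of 20 higher and 5 lower, did not pass either (2 and 2, and 6 and 6, adjusted over the list alone). The camera adjusted p of these 4 lists was 0.64, 0.796, 0.837 and 0.64. With 1 mouse left out in turn, the lower members numbered 0 without wt-139, wt-141, wt-146 or wt-176 for AP-1, 1 without wt-176 and 4 without cKO-152 for RNA polymerase III, 0 without wt-146 or wt-176 and 1 without wt-139, wt-141 or wt-175 for the immediate early genes, and 3 without wt-175 for the pan-neuronal genes.

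Among markers of other cells, 11 of 16 macrophage markers rose in wt (13 adjusted over the list alone; camera adjusted p = 1.28e-07, and adjusted p = 0.252 with an estimated correlation). The chemokine receptor gene Cx3cr1 rose from 0.466 ± 0.272 to 2.51 ± 1.15 CPM and the complement gene C1qb from 1.62 ± 0.592 to 4.23 ± 1.15 CPM. Of the interferon response genes 11 of 30 rose (11 adjusted over the list alone; camera adjusted p = 0.00496, and adjusted p = 0.783 with an estimated correlation), and of the proliferation markers 4 of 12 rose (7 adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.624 with an estimated correlation). The interferon count was 7 without wt-146, and the proliferation count 7 without wt-155 and 8 without wt-141 or cKO-194; the proliferation list did not pass within the mice with a low ribosomal share (adjusted p = 0.0602). Satellite glia had 2 of 14 markers higher, myelinating Schwann cells 1 of 14 and fibroblasts 1 of 12 (2, 0 and 1 adjusted over the list alone), and their lists did not pass, with camera adjusted p of 0.165, 0.826 and 0.488. The Schwann cell count was 0 without wt-172 and 2 without wt-176 or cKO-194, and the fibroblast count 2 without wt-176; the fibroblast list passed as higher within the mice with a low ribosomal share (adjusted p = 0.017). In the fit of all mice no marker of neutrophils, T and B cells, endothelial cells, pericytes and smooth muscle, red blood cells or skeletal muscle passed, also when adjusted over the list alone, with 10, 7, 13, 10, 7 and 3 measured. Neutrophil markers that passed numbered 2 without cKO-194 and 7 without wt-141. The neutrophil list, with a camera adjusted p of 0.108, passed without wt-141 or wt-155 (adjusted p = 0.0343 and 0.0405), in females (0.0282), within the mice with a high ribosomal share (0.012) and with no filter (0.027). For pericytes and smooth muscle the median was 0.11 while camera leaned lower (adjusted p = 0.843).

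In edgeR's quasi-likelihood test 5283 of 19565 genes changed with injury in wt, 2789 higher and 2494 lower, of which 719 rises and 44 falls reached 2-fold. With the mouse as a replicate block 8003 genes changed, 4072 higher and 3931 lower. Within the 11 mice with a high share of ribosomal RNA spacer counts 3121 genes changed and within the 6 with a low share 4163; the count was 2923 in females and 814 in males.

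**Figure D2:**
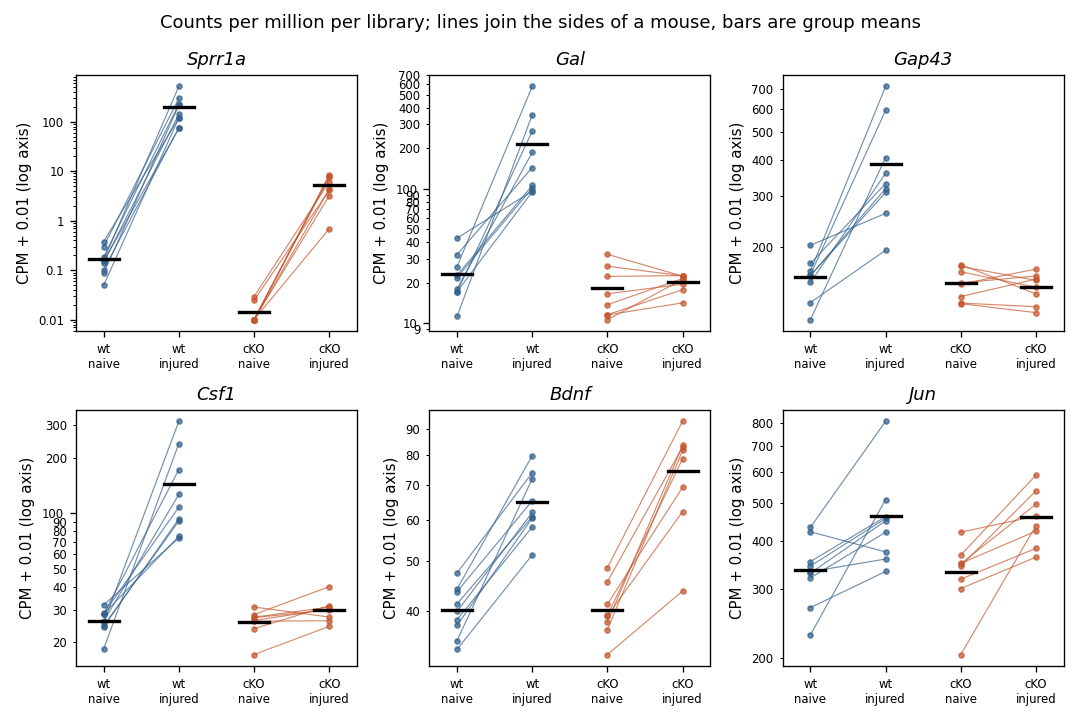
Level of 6 genes in each library, as CPM plus 0.01 on a log axis, with lines joining the sides of a mouse and bars at the group means. Sprr1a, Gal, Gap43 and Csf1 reach means of 198, 213, 387 and 144 CPM in injured wt and 5.29, 20.1, 145 and 30.2 CPM in injured cKO libraries; Bdnf reaches 64.9 and 74.4 CPM and Jun 464 and 461 CPM.

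The same comparison in ATF3-cKO asked what the response is without ATF3. Sprr1a rose in 8 of 8 mice, from 2 counts over all 8 naive libraries to 5.29 ± 2.70 CPM, and no fold is given at so few naive counts. Timp1, an inhibitor of metalloproteinases, rose from 0.425 ± 0.243 to 6.39 ± 1.95 CPM, the protease gene Ecel1 from 0.514 ± 0.200 to 6.62 ± 2.62 CPM and the orphan receptor gene Gpr151 from 0.966 ± 0.179 to 6.68 ± 2.25 CPM. The follistatin gene Fst and the metalloreductase gene Steap1 rose with log2 fold changes of 2.85 (SE 0.29, adjusted p = 2.5e-08) and 2.46 (SE 0.17, adjusted p = 5.72e-12). Cyp26b1 fell from 9.71 ± 3.21 to 4.98 ± 1.76 CPM and the serotonin receptor gene Htr3a from 174 ± 23.8 to 93.4 ± 21.5 CPM, each in 8 of 8 mice. The other named falls, Necab2, Pitpnm3, Rem2 and Bmpr1b, passed with all mice, but without mouse cKO-194 their adjusted p lay between 0.0522 and 0.199. Necab2 also did not pass without cKO-152, cKO-163 or cKO-192, Rem2 without cKO-130, cKO-152, cKO-156, cKO-163, cKO-192 or cKO-193, and Bmpr1b without cKO-130, cKO-131, cKO-152, cKO-163, cKO-192, cKO-193 or wt-195, each left out in turn (adjusted p of up to 0.0763, 0.155 and 0.199).

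Of the regeneration-associated genes 16 of 32 rose in cKO (17 adjusted over the list alone; camera adjusted p = 1.74e-25, and adjusted p = 0.04 with an estimated correlation). Sox11 rose from 26.6 ± 4.32 to 80.0 ± 29.2 CPM and the growth factor gene Bdnf from 40.2 ± 4.92 to 74.4 ± 15.6 CPM. The transcription factor gene Jun stood at 332 ± 62.5 and 461 ± 76.8 CPM (adjusted p = 0.0494), a call that ended in 13 of the 17 fits that leave out 1 mouse, those other than wt-141, wt-146, wt-172 and wt-176, with an adjusted p of up to 0.208. These fits ignore the pairing of sides, and Jun was higher on the injured side in every cKO mouse. Gal, Gap43 and Csf1 did not pass, with log2 fold changes of 0.15 (SE 0.33, adjusted p = 0.927), -0.04 (SE 0.17, adjusted p = 0.962) and 0.22 (SE 0.22, adjusted p = 0.763). These values too ignore the pairing of sides, so they do not show that the genes stayed unchanged. In single cKO mice the log2 injured to naive ratio of Csf1 ran from -0.18 to 0.506. Of the ATF4 targets 9 of 27 rose (15 adjusted over the list alone; camera adjusted p = 3.21e-11, and adjusted p = 0.04 with an estimated correlation), with Chac1 at 1.10 on the log2 scale; the count was 3 without cKO-163, 4 without cKO-152 and 5 without cKO-192 or cKO-194. Of the neuronal injury and death genes 6 of 19 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.52e-05, and adjusted p = 0.0947 with an estimated correlation), and 2 rose without cKO-163. Of the proliferation markers 1 of 12 rose (6 adjusted over the list alone; camera adjusted p = 7.15e-06, and adjusted p = 0.534 with an estimated correlation); the count was 0 without cKO-130, cKO-152, cKO-156, cKO-163, cKO-192 or cKO-194 and 2 without cKO-131, wt-141 or wt-146, and within the mice with a low ribosomal share the list did not pass (adjusted p = 0.0525). The potassium channel list leaned lower with 1 of 30 lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 7.15e-06, and adjusted p = 0.384 with an estimated correlation), and the lower ones numbered 0 without cKO-130, cKO-152, cKO-156, cKO-163 or cKO-194 and 7 without wt-176. The cholesterol synthesis list also leaned lower, though none of its 25 genes passed (0 adjusted over the list alone; camera adjusted p = 0.00421, and adjusted p = 0.595 with an estimated correlation); 1 passed without wt-175, and the list did not pass in males (adjusted p = 0.0541). The nociceptor list, lower, passed at a camera adjusted p of 0.041, with adjusted p = 0.926 with an estimated correlation and adjusted p = 0.0567 with the mouse as a block. It did not pass without cKO-152, cKO-163, wt-175, cKO-193 or cKO-194 (adjusted p of up to 0.104), nor in females, within the mice with a high ribosomal share, with that share as a covariate, with median-ratio size factors or in DESeq2 (adjusted p = 0.157, 0.134, 0.0895, 0.05 and 0.0723). Satellite glia went the other way, from adjusted p = 0.0819 to 0.0143 with the block, and passed in males (0.0307) and without cKO-131 or cKO-193 (0.0487 and 0.0231). None of the 16 macrophage markers passed in the fit of all mice, also when adjusted over the list alone. Their list, with a camera adjusted p of 0.0603, passed as higher without cKO-152, cKO-163, wt-172, cKO-192 or cKO-193 (adjusted p from 0.00322 to 0.0482). It also passed in males (0.0029), within the mice with a high ribosomal share (0.0177), with no filter (0.0271) and in DESeq2 (0.0196).

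Further lists of cKO lay near the threshold or rested on single mice. The interferon response list leaned higher, with 1 of 30 genes higher (2 adjusted over the list alone; camera adjusted p = 0.00914, and adjusted p = 0.926 with an estimated correlation); the count was 2 without cKO-131, wt-176 or cKO-192. It did not pass without cKO-194 (adjusted p = 0.0686) or in females (0.22). Of the mechanoreceptor and proprioceptor genes 1 of 20 was lower and 1 higher (5 and 1 adjusted over the list alone), and the lower ones numbered 0 without cKO-130, cKO-152, cKO-156, cKO-163 or cKO-194 and 2 without cKO-131, wt-150, wt-176 or cKO-193. Their list, with a camera adjusted p of 0.0523 and adjusted p = 0.926 with an estimated correlation, passed as lower without cKO-152, wt-155, cKO-163, wt-172, cKO-192, cKO-193 or wt-195 (adjusted p from 0.00211 to 0.0487). It passed too in males, within the mice with a low ribosomal share, with that share as a covariate and with no filter (adjusted p = 0.0068, 0.00212, 0.0478 and 0.02). Neutrophil markers had a median of 0.76 on the log2 scale, and none of the 10 passed, also when adjusted over the list alone (camera adjusted p = 0.0797, and adjusted p = 0.945 with an estimated correlation). Their list passed as higher without cKO-152, cKO-156 or cKO-193 (adjusted p from 0.015 to 0.037), in males (0.00055), within the mice with a high ribosomal share (0.00367), with no filter (0.0482) and in DESeq2 (0.0196). The neutrophil median was -0.05 without cKO-194, -0.07 in females and -0.15 within the mice with a low ribosomal share. With the mouse as a block 17 regeneration-associated genes and 14 ATF4 targets rose in cKO. Of the neuronal injury and death genes 8 rose and 1 fell there. Of the potassium channel genes 6 fell and 1 rose, of the mechanoreceptor and proprioceptor genes 4 fell and 1 rose, and of the cholesterol synthesis genes 3 fell and 1 rose.

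In cKO 624 genes changed in edgeR's quasi-likelihood test, 510 higher and 114 lower, and with the mouse as a replicate block 1643, 934 higher and 709 lower. Of the 510 rises 368 were also rises in wt, against 72.7 for independent lists, and of the 114 falls 86 were also falls in wt, against 14.5. The count was 378 without mouse cKO-152, 345 without mouse cKO-163 and 407 without mouse cKO-194, 133 and 384 within the mice with a high and a low ribosomal share, 973 with that share as a covariate, 126 in females and 99 in males.

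How much of the wt response each mouse showed was measured as the slope of its log2 injured to naive ratios on a wt signature that never used that mouse. Responses particular to cKO do not enter this slope. The slope was 0.387 ± 0.114 (SD, n = 8) in cKO and 0.962 ± 0.282 (SD, n = 9) in wt, a ratio of 0.403 (two-sided exact permutation p = 0.000123 over 24310 splits). For signature genes that rose in wt the ratio was 0.4 (exact permutation p = 0.000123), and for those that fell it was 0.502 (exact permutation p = 0.0203). The mean slope for rises and falls was 0.387 and 0.384 in cKO and 0.969 and 0.765 in wt. With signature genes of any size the ratios for rises and falls were 0.406 and 0.414 (exact permutation p = 0.000206 and 0.00629). The lowest wt slope, 0.549 in mouse wt-141, lay below the highest cKO slope, 0.556 in mouse cKO-194. Among the 11 mice with a high ribosomal share the ratio was 0.421 (exact permutation p = 0.00433), and among males 0.417, where 3 against 3 mice cannot give an exact permutation p under 0.1. The high-share signatures held a median of 40 genes, against 740 with all mice. The slope was not computed within the 6 mice with a low ribosomal share.

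**Figure D3:**
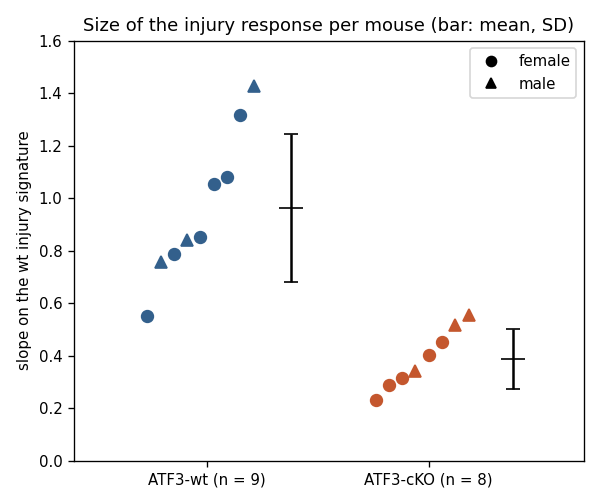
Slope of each mouse on the wt injury signature (no unit), with circles for females, triangles for males, and the mean and SD of each genotype at the right. The means are 0.962 in wt and 0.387 in cKO.

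The difference between the injury effects in cKO and wt was tested to find which responses depend on the genotype. Igfn1 (ENSMUSG00000051985, chromosome 1, 135953578 to 136006342) stood at 0.0642 ± 0.0434 CPM in naive and 5.78 ± 4.60 CPM in injured wt, and at 0.0620 ± 0.0378 and 0.0691 ± 0.0277 CPM in cKO, a log2 difference of -6.28 (SE 0.76, adjusted p = 6.1e-06). The membrane protein gene Tmem88b stood at 1.42 ± 0.279 and 34.3 ± 23.2 CPM in wt and at 1.46 ± 0.479 and 2.35 ± 0.713 CPM in cKO, a log2 difference of -3.91 (SE 0.42, adjusted p = 1.61e-06). Slc6a4, the activin receptor gene Acvr1c and Wfdc3 had log2 differences of -4.11, -3.61 and -3.24. Sprr1a and Npy, with naive totals of 2 and 4 counts in cKO, did not pass (adjusted p = 0.997 and 0.995). For a smaller set the value was higher in cKO. The potassium channel gene Kcng4 stood at 10.6 ± 3.72 and 7.58 ± 0.930 CPM in naive and injured wt and at 9.93 ± 2.18 and 22.4 ± 7.35 CPM in cKO, a log2 difference of 1.66 (SE 0.28, adjusted p = 0.000373). The protocadherin gene Pcdh18 stood at 9.36 ± 2.00 and 11.2 ± 1.19 CPM in wt and at 9.58 ± 1.85 and 27.2 ± 9.88 CPM in cKO. Racgap1, a regulator of cell division, stood at 7.79 ± 1.46 and 10.8 ± 1.24 CPM in wt and at 8.21 ± 1.20 and 25.3 ± 8.07 CPM in cKO. Chodl and Mrvi1 had log2 differences of 1.82 and 1.05.

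The injury effect was smaller in cKO for 14 of 32 regeneration-associated genes and larger for none (20 smaller adjusted over the list alone; camera adjusted p = 4.06e-28, and adjusted p = 0.0431 with an estimated correlation). The log2 differences were -3.06 for Gal, -1.35 for Gap43, -2.24 for Csf1 and -1.59 for the stress gene Gadd45a. Bdnf and Jun did not pass, with log2 differences of 0.19 (SE 0.14, adjusted p = 0.687) and 0.02 (SE 0.19, adjusted p = 0.997). The value was lower in cKO for 6 of 25 cholesterol synthesis genes (11 adjusted over the list alone; camera adjusted p = 2.22e-10, and adjusted p = 0.0531 with an estimated correlation) and for 6 of 21 tubulin and neurofilament genes (8 adjusted over the list alone; camera adjusted p = 7.84e-05, and adjusted p = 0.567 with an estimated correlation). The cholesterol synthesis count was 3 without cKO-152, wt-172 or cKO-193, and the tubulin and neurofilament count 3 without wt-172 or cKO-193. The value was lower for 5 of 17 neuropeptide genes and higher for 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.000164, and adjusted p = 0.0851 with an estimated correlation). The higher one was Cck, at 1.38, whose call ended in 5 of the 17 fits that leave out 1 mouse, those without cKO-130, wt-146, cKO-163, wt-175 and cKO-193, with an adjusted p of up to 0.0631. The value was lower for 2 of 16 macrophage markers (7 adjusted over the list alone; camera adjusted p = 3.67e-08, and adjusted p = 0.31 with an estimated correlation). These were Cx3cr1, at -1.89, and C1qb, at -1.29, whose call ended in 10 of these fits, those without wt-139, wt-150, cKO-152, wt-155, cKO-163, wt-172, wt-175, cKO-192, cKO-193 and cKO-194 (adjusted p of up to 0.114). The macrophage count was 4 without cKO-131 or cKO-156. The value was higher for 3 of 30 potassium channel genes (4 adjusted over the list alone; camera adjusted p = 3.67e-08, and adjusted p = 0.171 with an estimated correlation). The mechanoreceptor and proprioceptor list leaned higher, with 1 of 20 higher (1 adjusted over the list alone; camera adjusted p = 1.12e-05, and adjusted p = 0.327 with an estimated correlation); the count was 0 without wt-139, wt-150, cKO-163, wt-172, wt-175, cKO-192, cKO-193 or cKO-194 and 3 without cKO-131. The ribosomal protein list leaned lower, with 0 of 76 passing, also over the list alone (camera adjusted p = 2.49e-07, and adjusted p = 0.446 with an estimated correlation). The nociceptor list leaned higher, with 0 of 31 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.0186, and adjusted p = 0.816 with an estimated correlation). In the fits that leave out 1 mouse, 1 gene was higher without wt-141, wt-146 or wt-176, and a lower gene was found only without wt-141, wt-146, wt-155 or wt-195. The list did not pass without cKO-130, cKO-131, cKO-156 or wt-176 (up to 0.303), in males (0.078) or in DESeq2 (0.0856). None of the 27 ATF4 targets passed in the fit of all mice, also when adjusted over the list alone (camera adjusted p = 0.998), and 1 was lower without wt-141. The fibroblast list, lower in cKO, had a camera adjusted p of 0.0759 and passed with the mouse as a block (adjusted p = 0.0423), with no filter (0.0297), in females (0.0351) and within the mice with a low ribosomal share (0.0038). It also passed without cKO-130, cKO-131, wt-141, cKO-152, cKO-156, wt-176 or cKO-194 (adjusted p from 0.00615 to 0.0403). The member counts above come from the fit that ignores the pairing of sides. With the mouse as a block, 16 regeneration-associated, 14 cholesterol synthesis, 8 tubulin and neurofilament, 6 macrophage and 2 ribosomal protein genes were lower in cKO. In that fit 6 potassium channel and 7 mechanoreceptor and proprioceptor genes were higher, and 5 neuropeptide genes were lower and 1 higher.

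In edgeR's test the injury effect differed for 556 genes, 420 lower and 136 higher in cKO, and for 1474 with the mouse as a replicate block, 839 lower and 635 higher. Of the 420 genes 415 were rises in wt, against 59.9 for independent lists. Of the 136 genes 87 were falls in wt, against 17.3, and 50 were rises in cKO, against 3.5, so a higher value often went with a fall in wt. With cKO groups simulated around the observed wt means, without a change of the injury effect, no gene was lower. Of the 420 genes of lowest p among those with a lower value 39 to 60 were rises in wt over 10 draws. The chance deviations of the wt libraries enter these draws, so they cannot show what sharing the wt libraries gives. The real comparisons of injury in wt and of the difference do share them. With the wt mice split, 5 of them called 1022 rises, and these included 247 of the 311 genes that were lower in cKO against the other 4, against 17.1 for independent lists. With the parts exchanged the overlap was 87 of 201, against 2.3. For the genes higher in cKO, 4 of 20 were falls in the first part, against 0.6. With the parts exchanged it was 0 of 53, where only 10 falls were called. The count was 348 without mouse wt-139, 339 without mouse wt-172, 358 without mouse cKO-193 and 963 with the ribosomal share as a covariate, 650 lower and 313 higher. Within the mice with a high ribosomal share it was 48, 41 lower and 7 higher. Within those with a low share it was 3, 0 lower and 3 higher. The count was 67 in females, 65 lower and 2 higher, and 0 in males, where edgeR gave 870 genes at an unadjusted p under 0.05 and chance gives 964.

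**Figure D4:**
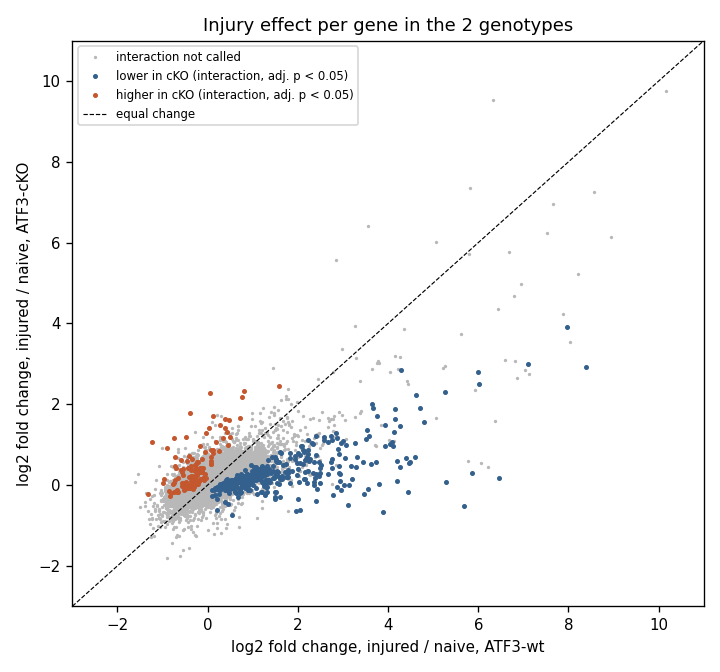
Injury effect of each gene as log2 fold change in ATF3-wt (x) and ATF3-cKO (y), coloured where the difference passed an adjusted p of 0.05, with the dashed line at equal change. The 420 genes with a lower value in cKO lie below the line and the 136 with a higher value above it.

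Between genotypes on the injured side, the comparison asked how the libraries of the crushed side differ, which are enriched for neurons but also hold other cells. Igfn1, Npy, Sprr1a, Cckbr, Fgf3 and Lipn were lower in cKO, with log2 fold changes of -6.29, -5.39, -5.24, -4.77, -4.55 and -4.31. Chodl, Kcng4, Pcdh18, Racgap1 and Mrvi1 were higher, with log2 fold changes between 1.19 and 1.73; within the mice with a high ribosomal share Chodl did not pass (adjusted p = 0.0673). The serpin gene Serpina3h was higher at 2.31 (SE 0.65, adjusted p = 0.0167), but stood at -0.06 in males and had an adjusted p of 0.0505 without mice cKO-131 and wt-150, 0.0593 with only the injured libraries, 0.279 without the sex covariate and 0.785 within the mice with a low ribosomal share. Of the regeneration-associated genes 23 of 32 were lower (25 adjusted over the list alone; camera adjusted p = 1.29e-36, and adjusted p = 0.0145 with an estimated correlation). Of the cholesterol synthesis genes 11 of 25 were lower (13 adjusted over the list alone; camera adjusted p = 1.24e-11, and adjusted p = 0.0293 with an estimated correlation), with Hsd17b7 at -1.59 and the squalene epoxidase gene Sqle at -0.36 on the log2 scale. Of the neuropeptide genes 8 of 17 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 2.13e-05, and adjusted p = 0.0293 with an estimated correlation). Of the macrophage markers 5 of 16 were lower (7 adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.554 with an estimated correlation), with an adjusted p of 0.138 in males. In all 2175 genes differed in edgeR's test, 698 higher and 1477 lower in cKO. Within the mice with a high and a low ribosomal share 972 and 1446 differed (240 higher and 732 lower, and 653 higher and 793 lower), with only the injured libraries in the fit 1112, in females 718 and in males 102.

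Other lists also leaned to one side on the injured side. Markers of neutrophils, proliferating cells and red blood cells had medians of 1.02, 0.77 and 1.11 on the log2 scale in cKO against wt, though none of the 10, 12 and 7 passed, also when adjusted over the list alone (camera adjusted p = 0.00338, 0.00486 and 0.049, and adjusted p = 0.554, 0.554 and 0.649 with an estimated correlation). With 1 mouse left out in turn, the neutrophil markers that passed numbered 4 without wt-146, and the proliferation markers 1 without wt-146, cKO-192 or cKO-193. Of the pan-neuronal genes 2 of 20 were lower, with a median of -0.12 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0487, and adjusted p = 0.554 with an estimated correlation). Avil is among these genes, and its median was lower in libraries labelled Cre-positive. Of the tubulin and neurofilament genes 9 of 21 were lower (10 adjusted over the list alone; camera adjusted p = 3.04e-07, and adjusted p = 0.424 with an estimated correlation). Ribosomal protein genes were lower for 3 of 76 (2 adjusted over the list alone; camera adjusted p = 0.00129, and adjusted p = 0.554 with an estimated correlation); this count was 1 without wt-172 or wt-176, 5 without wt-141 and 7 without cKO-194. Of the potassium channel genes 5 of 30 were higher (5 adjusted over the list alone; camera adjusted p = 3.24e-05, and adjusted p = 0.424 with an estimated correlation). Mechanoreceptor and proprioceptor genes were higher for 3 of 20 (7 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.554 with an estimated correlation); this count was 1 without cKO-152 or cKO-193 and 7 without cKO-131. The interferon response list leaned higher with 1 of 30 higher (1 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.7 with an estimated correlation). The nociceptor list also leaned higher, with 1 of 31 higher and 2 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.049, and adjusted p = 0.661 with an estimated correlation). The other cell type lists did not pass in the fit of all mice, with camera adjusted p from 0.067 to 0.583, and some passed in subsets. Within the mice with a low ribosomal share the Schwann cell and pericyte lists passed as lower in cKO, with medians of -0.60 and -0.99 (adjusted p = 0.00103 and 0.0191). Within the mice with a high share both passed as higher, with medians of 0.69 and 0.80 (adjusted p = 1.07e-05 and 0.000281). The endothelial, satellite glia and T and B cell lists also passed as higher there (adjusted p = 0.00558, 0.0157 and 0.0157). T and B cells passed with no filter and in DESeq2 too (adjusted p = 0.0206 and 0.0482). With 1 mouse left out, T and B cells passed without wt-139, cKO-156 or cKO-193 and endothelial cells without wt-176 (adjusted p down to 0.0275 and 0.0383).

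With 1 mouse left out in turn, the lower pan-neuronal genes numbered 4 without wt-141 or wt-175, and 1 was higher without cKO-194. The higher interferon response genes numbered 0 without wt-172 or wt-176 and 2 without cKO-131, wt-175, cKO-192 or cKO-194. The higher nociceptor genes numbered 2 without wt-155 or cKO-194 and 3 without wt-141, and the lower ones 1 without cKO-130, wt-139, wt-172, wt-176, cKO-192, cKO-193 or cKO-194. Several of these list calls rested on single mice or sets of mice. Without mouse cKO-194 the proliferating cell, red blood cell, pan-neuronal and interferon lists did not pass (adjusted p = 0.0812, 0.281, 0.166 and 0.258). The interferon list also did not pass without wt-141 (0.0896). The pan-neuronal list also did not pass without cKO-130, cKO-131, wt-146, wt-150 or wt-172 (up to 0.125). The red blood cell list also did not pass without cKO-130, cKO-131, wt-141, wt-146, wt-150, wt-155, wt-172, wt-175 or wt-176 (up to 0.149). The nociceptor list did not pass without cKO-130, cKO-131, wt-139, cKO-152, cKO-156, wt-172, wt-175, wt-176, cKO-192 or cKO-193 (up to 0.321). In females the neutrophil, proliferating cell, red blood cell, pan-neuronal and interferon lists did not pass (adjusted p = 0.0973, 0.0597, 0.0775, 0.0887 and 0.0597). Within the mice with a low ribosomal share the red blood cell, pan-neuronal, interferon and nociceptor lists did not pass (adjusted p = 0.416, 0.435, 0.668 and 0.0731). The interferon median was -0.064 there, against 0.239 with all mice. Without mice cKO-131 and wt-150 the red blood cell, pan-neuronal and nociceptor lists did not (0.141, 0.112 and 0.0758). The pan-neuronal call also ended with only the injured libraries in the fit (0.0584) and in DESeq2 (0.0592). The red blood cell call also ended with median-ratio size factors (0.0505) and with the ribosomal share as a covariate (0.0749). The nociceptor call ended under these 4 alternatives, in males and within the mice with a high share (adjusted p from 0.0505 to 0.534).

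**Figure D5:**
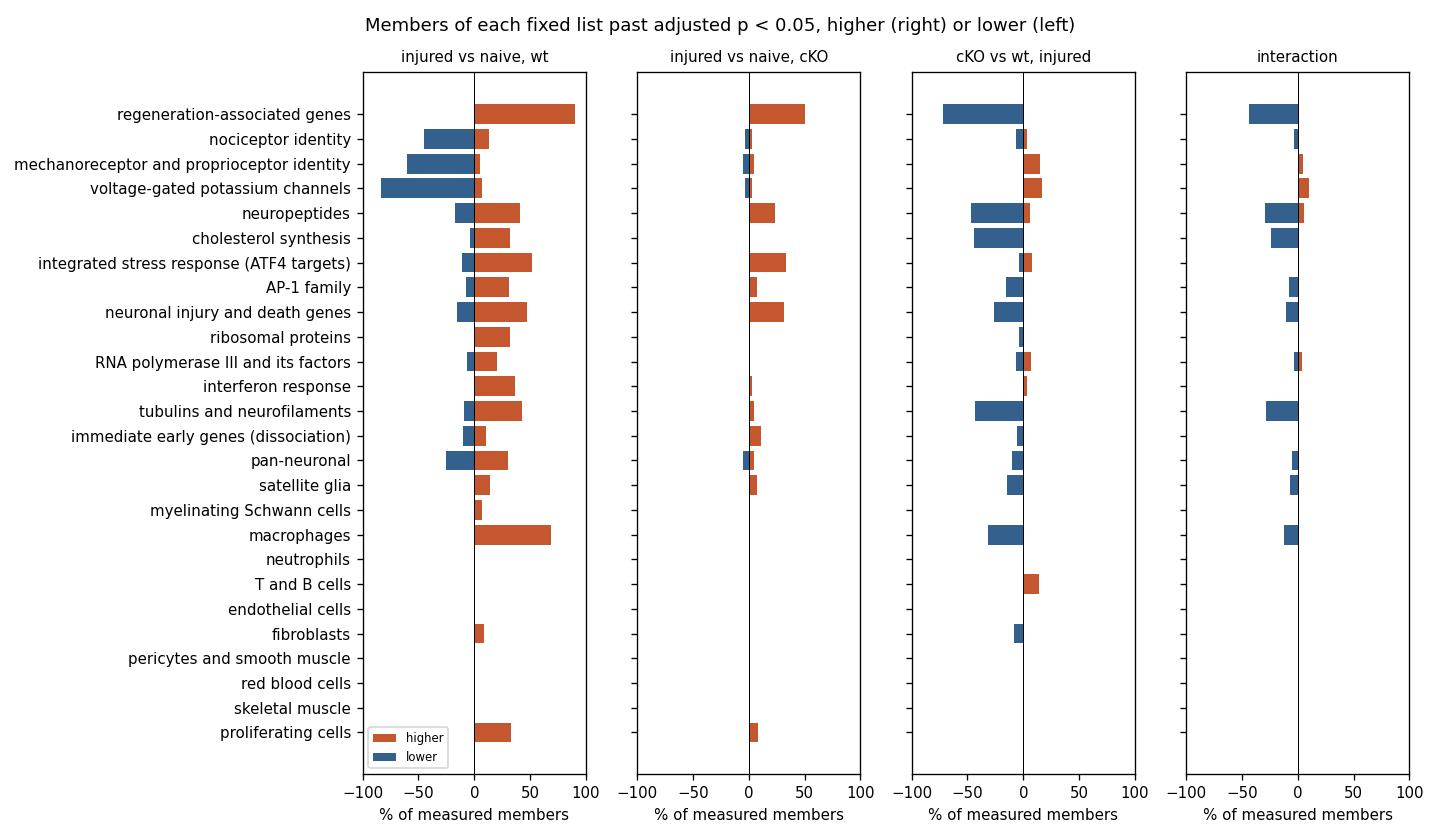
Share of the measured members of each fixed list that passed an adjusted p of 0.05, in percent, drawn to the right where higher and to the left where lower, for 4 comparisons. Regeneration-associated genes lie to the right in wt, with 29 of 32, and to the left for cKO against wt on the injured side, with 23 of 32.

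On the naive side, which is the other side of the crushed mice and not uninjured animals, the comparison of genotypes gave the background for the injured side. In it 0 genes passed in edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 506 genes, where chance gives 978, and DESeq2 called 1 gene, Sprr1a, lower in cKO. Within the mice with a high and a low ribosomal share the count was 0, with 527 and 783 genes at an unadjusted p under 0.05. Neutrophil markers had a median log2 fold change of 1.38 in cKO (10 of 10 higher adjusted over the list alone; camera adjusted p = 5.29e-20, and adjusted p = 0.0781 with an estimated correlation). Interferon response genes had a median of 0.34 (0 adjusted over the list alone; camera adjusted p = 1.53e-20, and adjusted p = 0.118 with an estimated correlation), which was 0.02 within the mice with a low ribosomal share (adjusted p = 0.21). Red blood cell genes had a median of 1.18 (0 adjusted over the list alone; camera adjusted p = 7.67e-09, and adjusted p = 0.118 with an estimated correlation), and of 0.40 without mice cKO-131 and wt-150.

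The regeneration-associated list leaned lower in naive cKO, with a median of -0.06 and a mean of -0.40 on the log2 scale, and 0 of 32 genes passed (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000965, and adjusted p = 0.495 with an estimated correlation). In males its median was 0.003 while camera leaned lower. Smaller shifts of other lists also passed on the naive side, with no member past the threshold, also over the list alone. Mechanoreceptor, potassium channel, tubulin and pan-neuronal genes leaned lower, with medians of -0.07, -0.07, -0.06 and -0.04 (camera adjusted p = 0.00563, 0.00533, 0.00598 and 0.0129). Ribosomal proteins, satellite glia, Schwann cells and fibroblasts leaned higher, with medians of 0.05, 0.23, 0.17 and 0.32 (camera adjusted p = 0.000101, 0.0126, 0.00666 and 0.00494). Avil is a member of the pan-neuronal list on this side too. With an estimated correlation the adjusted p of these 8 lists lay between 0.495 and 0.544. Without mouse cKO-131, 7 of these 8 lists did not pass, all but the ribosomal proteins. Single omissions that also ended a call were cKO-194 for potassium channels, wt-175 for mechanoreceptors, wt-146 and wt-150 for tubulins, wt-146, wt-172 and cKO-194 for pan-neuronal genes, cKO-130, wt-172 and cKO-194 for satellite glia, wt-139, wt-141, wt-172 and cKO-194 for Schwann cells and wt-172 and cKO-193 for fibroblasts (adjusted p of up to 0.992 over the 7 lists). The same 7 did not pass without mice cKO-131 and wt-150 (adjusted p from 0.0708 to 0.987). In the set with a low ribosomal share mechanoreceptors, potassium channels, tubulins, pan-neuronal genes, ribosomal proteins and satellite glia did not pass (adjusted p from 0.152 to 0.84), and Schwann cells passed as lower (0.0499). In males mechanoreceptors, tubulins, pan-neuronal genes, ribosomal proteins, satellite glia and Schwann cells did not pass (adjusted p from 0.166 to 0.955).

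Over the 5 comparisons 59 list tests passed with the preset correlation and 7 with an estimated one: the regeneration-associated genes in all but the naive comparison, the ATF4 targets for injury in cKO, and the neuropeptide and cholesterol synthesis genes between genotypes on the injured side.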

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

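The tests of a common ratio, of the pan-neuronal genes on the injured side, of Cre, of a swap and of the share of neurons in injured wt were chosen after the result was seen. Of 170 groups of levels, shares and slopes 19 held a mouse far from the rest, where chance gives about 1 in 20.

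The injury effect differed between genotypes for 556 genes, and the response along the wt signature was smaller in cKO, with a slope ratio of 0.403. A weaker injury, if it scaled every gene alike, would leave genes at 1 common ratio of the cKO to the wt rise. The rise here is the fold change less 1, on a linear scale, so its ratio cannot be set against the slope ratio of log2 values. The common ratio was the median over the genes that rose at least 2-fold in wt. With that ratio at 0.233, 53 of the 719 genes that rose at least 2-fold in wt (7.4%) lay above it at an adjusted p under 0.05 and 35 (4.9%) below. This argues against a single ratio for every gene, though the bound of 5%, which was chosen and is not an error rate, was passed by little. A weaker injury that does not scale all genes alike was not tested. Fewer neurons in the injured cKO libraries would lower pan-neuronal genes as much as the 420 genes, but their median was -0.116 (SD 0.262 over 20 genes), against -0.914; the pan-neuronal list did lean lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0487, up to 0.166 with 1 mouse left out, and adjusted p = 0.554 with an estimated correlation), so a small part stays open. The 20 genes include Avil, with a median of 485.8 CPM in Cre-positive and 881.6 CPM in Cre-negative libraries, so this difference enters their SD and list test. The 420 genes were chosen for a lower injury effect in these same libraries, so the size of their median is likely overstated. Cre alone would bring Cre-positive wt slopes down to those of cKO, but they were 0.758 to 1.427 against 0.229 to 0.556 (two-sided exact permutation p = 0.00606, 3 against 8 mice), with sex not balanced between these sets. The loss of ATF3 is the design's biological explanation and remains a hypothesis, and a partly weaker injury stays open.

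Avil lay at 83.39 CPM in the naive and 88.78 CPM in the injured library of mouse cKO-131, where the nearest other cKO mice had 476.8 and 432.5 CPM. Fewer neurons in mouse cKO-131 would lower the other pan-neuronal genes alike, but their median difference from the other cKO mice was -0.26 (SD 0.606 over 19 genes), against -2.48 for Avil. Mouse wt-150, labelled Cre-negative, had Avil among the Cre-positive mice, and a swap with a mouse of this series would need a partner, but 0 Cre-positive mice lay in the range of the other Cre-negative mice, 792.5 to 1036 CPM. A single wrong Cre label of mouse wt-150 and a different Avil allele in mouse cKO-131 were not tested, nor was a biological explanation.

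Macrophage markers rose in injured wt, with a median of 1.38 on the log2 scale. A lower share of neurons there would raise other cell types alike, but the medians of 4 of 4 other lists lay below by more than the spread of the macrophage members (SD 0.584): satellite glia 0.20, Schwann cells 0.13, endothelial cells 0.13 and fibroblasts 0.16; of the 6 further cell type lists 4 had medians of 0.11 to 0.32, while neutrophils (1.10, and -0.14 within the mice with a low ribosomal share; camera adjusted p = 0.108, and 0.0343 and 0.0405 without mouse wt-141 and mouse wt-155) and proliferating cells (0.85, camera adjusted p = 0.00412) lay within that spread, so the types moved apart and a rise of these 2 beside macrophages stays open. The proliferating cell list had an adjusted p of 0.624 with an estimated correlation and did not pass within the mice with a low ribosomal share. Whether the macrophage markers follow the Csf1 rise of the mouse was left open by correlations in both genotypes, and no other biological explanation was tested. Over 9 wt mice Pearson r was 0.27 (exact permutation p = 0.477, adjusted p = 0.954), Spearman rho 0.367 (exact permutation p = 0.336) and r 0.434 without the 2 mice farthest in Csf1; over 8 cKO mice r was 0.005 (exact permutation p = 0.991, adjusted p = 0.991) and rho 0.119 (exact permutation p = 0.793), with r 0.219 without the 2 farthest.

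In injured wt libraries, mouse wt-172 had 515 CPM of Sprr1a and 13.99 CPM of Pcdh18, above the others. Mouse wt-176 had 809.9 CPM of Jun and 136.9 CPM of Npy, above the others, and 131.5 CPM of Kcna2, below them. Mouse wt-175 had a mean of 4.647 log2 CPM over Schwann cell markers, above the others. In naive wt libraries, mouse wt-141 had 2.328 CPM of Ecel1 and a mean of 2.845 log2 CPM over red blood cell genes, and mouse wt-146 had 22.06 CPM of Gadd45a, all above the others. Mouse wt-172 had a mean of -0.063 log2 CPM over macrophage markers, below the others. In naive cKO libraries, mouse cKO-131 had 1.252 CPM of Cx3cr1 and 17.38 CPM of Cyp26b1, above the others, and a mean of 8.272 log2 CPM over pan-neuronal genes, below them. Mouse cKO-152 had 36.64 CPM of Sox11, above the others, and mouse cKO-163 had 0.03095 CPM of Slc6a4, below them. In injured cKO libraries, mouse cKO-194 had 40.09 CPM of Csf1 and mouse cKO-131 had 5.079 CPM of C1qb, above the others.

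Other splits of the mice were refitted, 100 for each comparison with the real one included; for the injury effects each split kept the sides of a mouse apart and swapped them in some mice, and the highest others swapped 1 mouse. For injury in wt 1 split, the real one, gave 5283 genes and the highest other gave 3587. For injury in cKO 1 split, the real one, gave 624 and the highest other 301. For the difference of injury effects 1 split, the real one, gave 556 and the highest other 349. For genotype on the injured side 2 splits gave at least the real 2175; the other, with 2692, moved 7 wt mice into the cKO set and is close to the mirror of the real split. Only 1 or 2 of 100 splits reached these 4 counts, so a random grouping rarely gives as many genes. So few splits cannot exclude chance. On the naive side the real count was 0, which all 100 splits reach by construction, so the splits say nothing of chance there. The highest, with 2000 genes, put all 6 mice with a low ribosomal share in 1 set, so that share is a structure of the samples. That set held 3 females, so it also followed sex in part, which the fit holds as a covariate. Within the high and the low ribosomal set edgeR's naive count was 0, with 527 and 783 genes at an unadjusted p under 0.05 and DESeq2 not run there.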

How the results depend on the processing

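The fits within mice of 1 ribosomal share, that share as a covariate and the omission of mice cKO-131 and wt-150 were chosen after seeing the data. Counts stayed within 1.5 times with median-ratio size factors, no filter, no sex covariate and, except on the naive side, DESeq2. With the mouse as a replicate block the counts were 8003 for injury in wt, 1643 for injury in cKO and 1474 for the difference of effects. Of the single-gene results 306 stayed the same with the block and 38 became stronger. The block changed the nociceptor and satellite glia lists in cKO and the fibroblast list in the difference, and no other list call of those 3 comparisons. In females the counts were 2923, 126 and 67, and in males 814, 99 and 0. Genotype on the injured side gave 718 genes in females, 102 in males and 1112 with only the groups compared. Fewer samples were fitted in each of these subsets. On the naive side females gave 2 genes, Serpina3f and Serpina3h, and DESeq2 gave 1, Sprr1a; these names were chosen after their values were seen.

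Mice with a high ribosomal share gave 3121, 133 and 48 genes for injury in wt, injury in cKO and the difference, and 972 for genotype on the injured side. Mice with a low share gave 384 for injury in cKO, 1446 for genotype on the injured side and 3 for the difference, all higher in cKO, among them Chodl and Frmpd3, named after their values were seen. With the share as a covariate injury in cKO gave 973 and the difference 963; the cause was not tested. With each mouse left out in turn the counts were 4149 to 5587 for injury in wt, 345 to 926 for injury in cKO, 1525 to 2454 and 0 for genotype on the injured and naive sides, and 339 to 717 for the difference. The ratio of response sizes was 0.373 to 0.44 with each mouse left out and 0.37 to 0.438 under the other alternatives, and 0.417 in males lost the threshold because 3 against 3 mice cannot pass it. It was not computed within the mice with a low ribosomal share.

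List tests that passed fell from 59 to 7 with an estimated correlation, and were 50 to 64 with each mouse left out. Directions reversed for Serpina3h on the injured side in males (-0.062), and with a low ribosomal share for Schwann cells (-0.599, adjusted p = 0.00103) and pericytes (-0.985, adjusted p = 0.0191) on the injured side, which passed as lower. On the naive side that share reversed the lists of mechanoreceptors (0.059), tubulins (0.028), pan-neuronal genes (0.019), satellite glia (-0.171), Schwann cells (-0.168), endothelial cells (-0.378) and pericytes (-0.314), of which Schwann cells, endothelial cells and pericytes passed (adjusted p = 0.0499, 0.0028 and 0.0389); leaving out mice cKO-131 and wt-150 reversed mechanoreceptors (0.032) and tubulins (0.009); the cause was not tested. With all mice the naive endothelial and pericyte lists leaned higher, with medians of 0.21 and 0.126, and did not pass (camera adjusted p = 0.0612 and 0.352). Endothelial cells passed as higher without cKO-152, wt-155, cKO-163, wt-175, wt-176, cKO-192 or wt-195 (adjusted p from 0.000543 to 0.0489). Pericytes passed as higher without cKO-163 (0.0392). The planned test of B2-SINE elements and its library-size alternative were not run. Depth limits genes with few naive counts, such as Sprr1a and Lipn with 2 counts each over the naive cKO libraries.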

Other observations

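The test of sex, the sets by ribosomal share and the omission of mice cKO-131 and wt-150 were chosen after the data were seen. On the naive side, 4 regeneration-associated genes passed between genotypes when adjusted over the list alone, and none over all genes. Cckbr had a log2 fold change of -2.64 (SE 0.78, adjusted p = 0.0268 over the list alone) and Npy of -4.69 (SE 1.41, adjusted p = 0.0268 over the list alone), on 16 and 4 counts over the naive cKO libraries. Sprr1a had 88 counts over the 9 naive wt and 2 over the 8 naive cKO libraries (adjusted p = 0.0268 over the list alone). Anxa1, the annexin A1 gene, was higher at 1.23 (SE 0.42, adjusted p = 0.0458 over the list alone). The adjusted p of all 4 was 1 over all genes, and no explanation was tested. Whether each gene passed over the list alone rested on single mice, but the sign of its change did not. With 1 mouse left out in turn, the log2 fold change was -2.851 to -2.229 for Cckbr, -5.33 to -3.854 for Npy and 0.982 to 1.498 for Anxa1. Sprr1a had counts in every naive wt library and none in 6 of the 8 naive cKO libraries. Npy stood at 0.258 CPM in naive wt, and at 0.134 CPM without mouse wt-150, where its log2 fold change was -3.85 (adjusted p = 0.0889 over the list alone). With 1 mouse left out in turn, Npy did not pass over the list alone without wt-150, cKO-152, wt-155, cKO-156 or cKO-193, Cckbr without cKO-152, cKO-156, wt-176 or cKO-193, Sprr1a without cKO-152, wt-155, cKO-156, wt-176 or cKO-193, and Anxa1 without cKO-131, wt-139, wt-146, wt-150, cKO-152, wt-155, cKO-156, wt-172, wt-175, wt-176, cKO-193 or wt-195 (adjusted p of up to 0.0889, 0.0591, 0.0591 and 0.171). None of the 4 passed over the list alone in females (0.0801 to 0.339), in males (0.261 to 0.999), within the mice with a high (0.358 to 0.548) or a low ribosomal share (0.457 to 0.804), or with that share as a covariate (0.0578 for each). Npy and Anxa1 did not pass without mice cKO-131 and wt-150 (0.098 and 0.201), and Anxa1 did not with no filter (0.0584) or only the naive libraries (0.0676), where the other 3 were filtered out.

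Proliferation markers had a naive median of 0.72 on the log2 scale in cKO against wt (0 adjusted over the list alone; camera adjusted p = 2.8e-13, and adjusted p = 0.118 with an estimated correlation), macrophage markers of 0.38 (0 adjusted over the list alone; camera adjusted p = 1.17e-08, and adjusted p = 0.245 with an estimated correlation) and T and B cell markers of 0.54 (0 adjusted over the list alone; camera adjusted p = 0.000157, and adjusted p = 0.118 with an estimated correlation). Without mice cKO-131 and wt-150 these medians were 0.44, 0.21 and 0.37. The T and B cell list did not pass in males or within the mice with a low ribosomal share (adjusted p = 0.054 and 0.054).

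Whether the injury effect differed between sexes was also tested. In edgeR's quasi-likelihood test 0 genes passed in wt, with 85 at an unadjusted p under 0.05, and 0 in cKO, with 207, where chance gives 978. These fits ignore that the sides of a mouse are paired; with the mouse as a replicate block 0 genes passed in either genotype, with 256 and 319 at an unadjusted p under 0.05. Each of these counts is below that of chance, and they do not show that the sexes respond alike. No other tool was run for it, and in wt sex cannot be separated from Cre.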
